A study of Mus musculus with 8 samples.

How the data were processed

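MS1 is an established mouse endothelial cell line derived from pancreatic islets. Per the labels' protocols, MS1 cells were serum starved for 24 h and then received fresh medium or recombinant BMP9/10 at 1 ng/mL. BMP9 and BMP10 are circulating ligands of the endothelial receptor ALK1, and SMAD4 is the common partner of the receptor-activated SMADs. Chromatin was fragmented by sonication and immunoprecipitated with a SMAD4 antibody, per the labels' protocols, and libraries were made from 10 ng of DNA. There were 8 samples in 4 groups of 2: SMAD4 immunoprecipitates (IP) and input DNA from unstimulated cells, and the same from stimulated cells. The titles of the stimulated IP libraries also carry the letters KD, whose meaning the labels do not give, while their other fields describe SMAD4-bound DNA from stimulated cells. Values from those libraries are therefore those of the libraries labelled as stimulated SMAD4 IP.

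The deposited files were 1 list of narrow peaks per condition, called by the authors with MACS2 2.1.0.20140616, per the file headers. Each list came from the 2 IP libraries merged into 1 set, against the 2 input libraries merged likewise, per the file headers, so no value per replicate was analysed here and no peak has a replicate error. Per the file headers, 52971023 IP tags and 72688953 input tags remained after filtering for the unstimulated list and 41044888 and 59057559 for the stimulated list. The authors kept at most 1 tag per position, extended each tag to 100 bp, sampled the larger set down to the smaller, used a q cutoff of 0.01 and took the local background over 2 window sizes, per the file headers. The tags were 146 bp (unstimulated) and 140 bp (stimulated) long, longer than the extension, and the caller's alternative fragment estimates were 171 and 187 bp, per the file headers, so widths and pileups describe 100 bp pieces of longer fragments. The band width setting differed between the lists (300 and 200), per the file headers. The submitters' processing notes name mm10, MACS2 and HOMER, and the aligner is not given in the sources used here.

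Pileup is a coverage signal, the number of extended tags over the summit, which the authors deposited without scaling to depth. In both lists the input was the larger set, so the pileups stand on all IP tags, and they were divided here by the IP tags of the list, and given per 1000000 IP tags, to set them side by side. The deposited −log10 p and −log10 q values come from the authors' comparison of IP with input. The deposited fold enrichment is the authors' ratio of pileup plus 1 to local background plus 1, and it was used to describe and rank peaks. Positions and widths are in bp on mm10, 1-based, as the authors deposited them. The local background was recovered from pileup and fold enrichment, and a Poisson tail computed from it came within 1% of the deposited p-value, on the −log10 scale, for all 1133 and all 4333 peaks.

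Gene positions came from a RefSeq table of GRCm38.p6, the assembly behind mm10, with 21887 protein-coding genes on the assembled chromosomes. The table gives no strand, so the planned distance to a transcription start site was replaced by the distance to the nearer end of a gene (within 1 kb) and to the nearest gene body (within 100 kb, 0 inside, ties kept). No genome sequence was used here, so the planned searches for SMAD motifs, motif spacing and 6-mers were not run. Peaks on mitochondrial DNA entered no gene or placement test.

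Peaks were counted as shared when they overlapped by at least 1 bp (bedtools 2.31.1). The overlap was set beside 1000 random placements of the unstimulated peaks on their own chromosomes (one-sided permutation test, whose smallest possible p is 0.001). Shares near gene ends were compared between the peaks of the lists with Fisher's exact test, two-sided. For 17 gene lists fixed before the data were examined, the number of genes that were nearest to a peak was set beside 10000 random lists of the same size, matched on 10 bins of the sequence a gene can collect peaks from. These one-sided permutation p-values were adjusted by Benjamini-Hochberg over all lists and both conditions. For the stimulated list shortened to the length of the unstimulated one, the adjustment ran over the 17 lists of that set alone. The same holds for stimulated peaks that overlap no unstimulated peak. Those adjusted values therefore stand on fewer tests than the others. The tests compare lists of peaks, not replicated conditions. Intervals of shares are exact binomial at 95%, intervals of pileup ratios are exact binomial on the 2 pileups, and both cover counting error within the pooled libraries only. On simulated data, 3% of 200 random lists had a p of 0.05 or less, all 20 lists planted among peaks were found, and all 600 planted overlaps were recovered. The planted lists had many members given a peak, and the planted overlaps were near copies of stimulated peaks. Both were easy to find, so they check the code and not the power for smaller effects. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

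The genes named were fixed before the data were examined: 16 genes of BMP and endothelial biology, the nearest genes of the 15 stimulated and 8 unstimulated peaks of highest fold enrichment, and up to 4 members of each list with the highest stimulated fold enrichment. Other genes are named where a count called for it, after their values were seen. Alternatives were stricter −log10 q minimums, other definitions of overlap, other gene distances, a stimulated list shortened to the length of the unstimulated one, and, added after the data were seen, another random model, curated genes, stimulated peaks that overlap no unstimulated peak, and lists without tall narrow peaks.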

Results

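SMAD4 binding was mapped by ChIP-seq in MS1 mouse endothelial cells without added ligand and after BMP9/10. Each condition had 2 IP and 2 input libraries, which the authors merged before calling peaks. The unstimulated list held 1133 peaks from 52971023 IP tags and the stimulated list 4333 peaks from 41044888 IP tags. The titles of the stimulated IP libraries carry the letters KD, which the labels do not explain. All values are those of pooled libraries, so differences between the conditions have no replicate check, and the p-values given compare lists of peaks, not replicated conditions.

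The first comparison asked where SMAD4 was bound with and without the ligand. SMAD4 peaks lay beside the classical BMP target genes in both conditions. Near Id3, which encodes an inhibitor of DNA binding, there were 4 unstimulated and 6 stimulated peaks. Smad6 and Smad7, the inhibitory SMADs, had 5 and 2 unstimulated and 7 and 7 stimulated peaks. Id1 had 3 peaks in each list, and Id2 had 2 and 3. Dll4, a Notch ligand of arterial endothelium, had 0 unstimulated and 4 stimulated peaks. These are counts of called peaks, and whether neighbouring peaks are separate sites was not tested.

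The strongest Id3 peak (mm10 chromosome 4, 136147946 to 136148190, 2.64 kb from the gene body) had a fold enrichment over input of 12.5 in the stimulated list. Its unstimulated counterpart had 7.08 in that list. The strongest stimulated Smad6 peak covered the end of the gene body (chromosome 9, 64021792 to 64022166) with a fold enrichment of 13.0, against 4.50 in the unstimulated list. At Smad7, a peak 0.215 kb outside the gene body (chromosome 18, 75366438 to 75367227) had 10.0 in the stimulated list, and its unstimulated counterpart had 7.49. Id1 was flanked by stimulated peaks of 10.3 (chromosome 2, 152735040 to 152735424) and 10.0 (152739363 to 152739678), with unstimulated values of 7.23 and 4.89. At Id2 the strongest stimulated peak (chromosome 12, 25098585 to 25099092) had 12.6, and the unstimulated list gave 6.14 there. Fold enrichment also follows the local background, which was lower in the stimulated list at the Smad6 and Id2 sites. The ratio of IP pileup per tag, stimulated over unstimulated, was 1.77 (counting interval 1.12 to 2.82) there at Smad6 and 1.51 (0.977 to 2.33) at Id2. Id4 had 1 peak in each list, 33.2 kb from the gene body on chromosome 13, with fold enrichments of 21 (stimulated) and 12.5 (unstimulated).

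**Figure D1:**
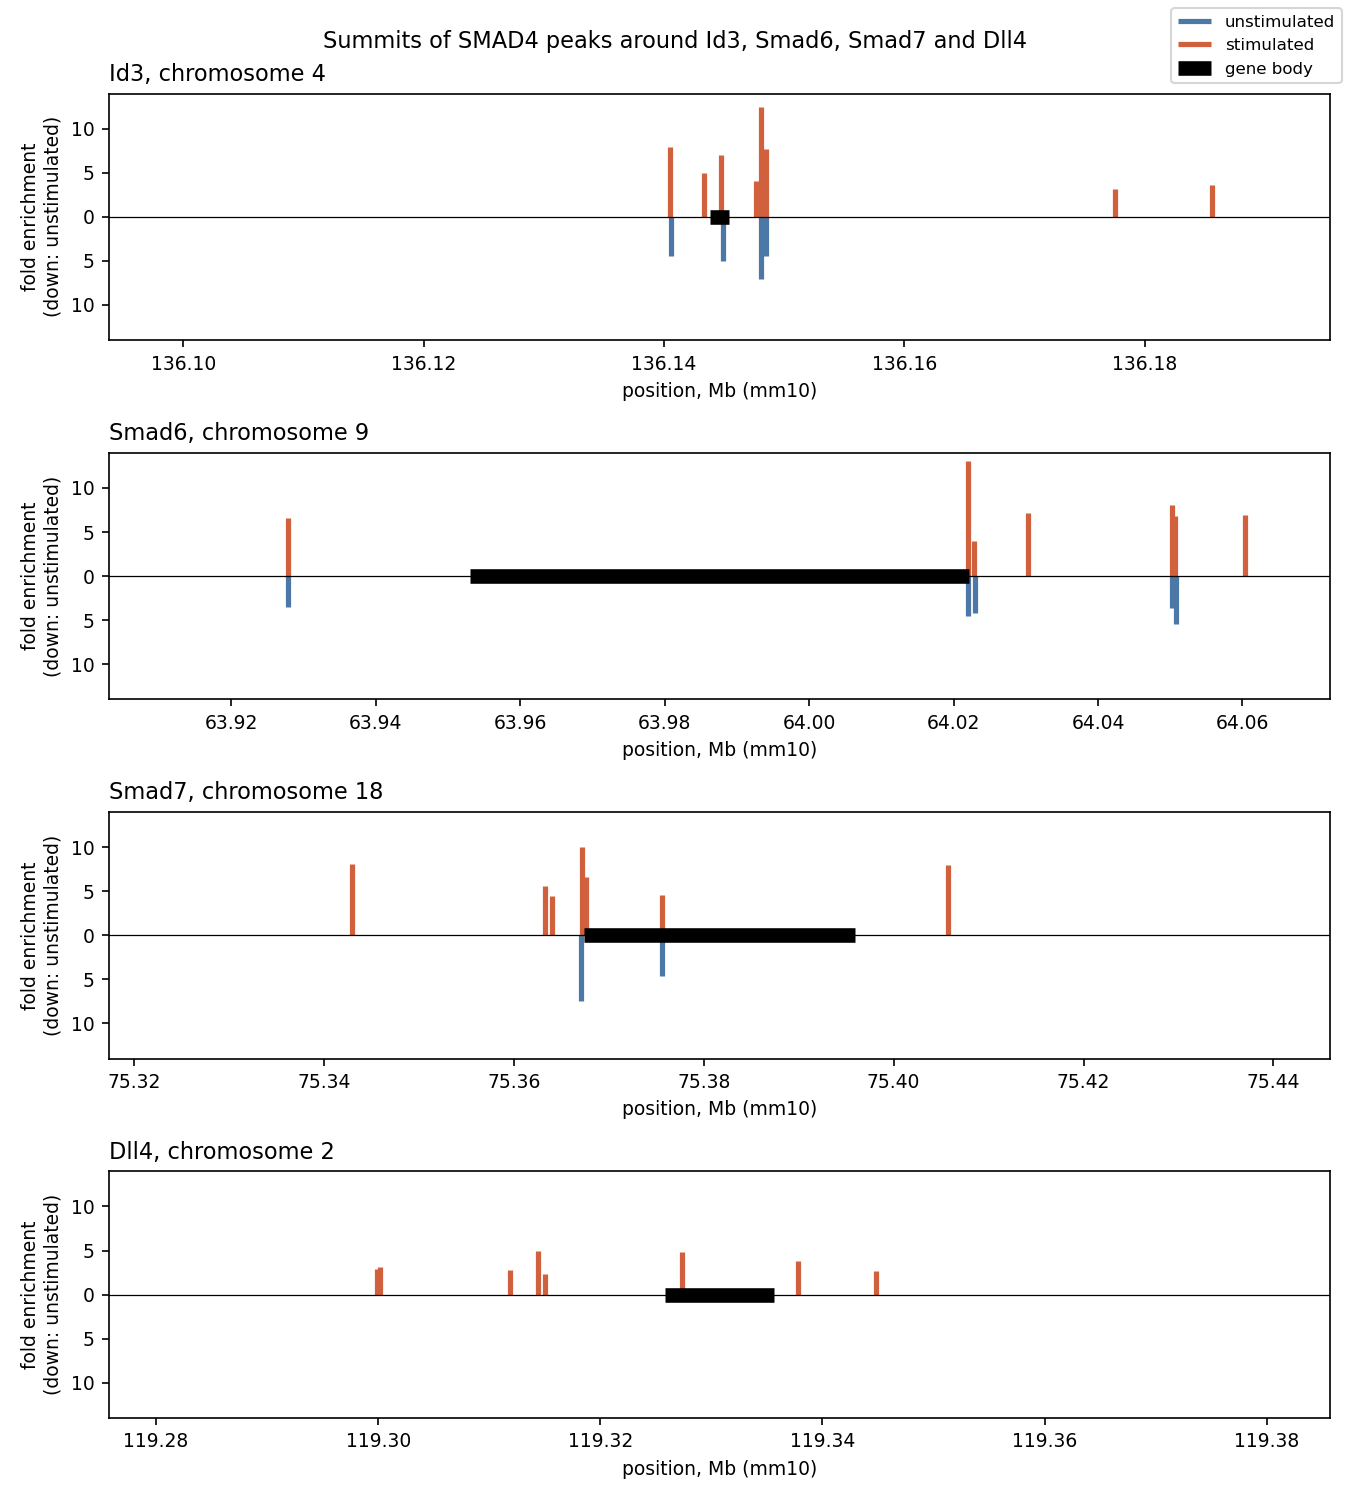
Summits of SMAD4 peaks around Id3, Smad6, Smad7 and Dll4, with mm10 position in Mb on the x axis and the authors' fold enrichment over input on the y axis, stimulated upward and unstimulated downward; black bars are gene bodies. Smad7 has 2 unstimulated and 7 stimulated peaks, and the window around Dll4 holds stimulated peaks and 0 unstimulated ones.

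Of the receptors and vascular genes fixed in advance, Eng, which encodes the BMP9/10 co-receptor endoglin, had 2 peaks inside its gene body in each list (stimulated fold enrichments 4.67 and 4.45, unstimulated 4.15 and 5.29). Kdr, the main VEGF receptor, had 2 unstimulated and 7 stimulated peaks. The strongest lay 10.0 kb from the gene body (chromosome 5, 75922584 to 75923109) with a stimulated fold enrichment of 7.50. Stimulated Kdr peaks without an unstimulated counterpart lay inside the gene body, 35.0 kb from it and, for most of them, 72.7 kb or more from it. These distant peaks were counted because Kdr was the nearest gene within 100 kb. Klf2, a flow-responsive transcription factor, had 1 and 2 peaks, and the shared peak on chromosome 8 (72310905 to 72311248) had 6.86 in the stimulated list. Bmpr2 had a stimulated peak of 4.60 in its gene body (chromosome 1, 59765429 to 59765615) and 0 unstimulated peaks. Tek, the angiopoietin receptor, had 2 stimulated peaks in its gene body (3.46 and 4.0) and 0 unstimulated ones. The stimulated peak inside Angpt2 (chromosome 8, 18711716 to 18711984, fold enrichment 4.13) was not called in the unstimulated list, and it also lies inside Mcph1. Unstimulated peaks 26.2 and 29.3 kb from Angpt2 (3.89 and 4.0) were shared with stimulated ones (7.26 and 4.50). These were nearest to Mcph1 and were therefore not counted for Angpt2. The strongest Dll4 peak (chromosome 2, 119314235 to 119314466) had 5.0 and lay 11.4 kb from the gene body. A stimulated peak 0.604 kb from Hey1 (fold enrichment 6.26) was nearest to a predicted gene and was therefore not counted for Hey1. No peak of either list lay within 50 kb of Smad9, Hey2 or Acvrl1.

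The peaks of highest fold enrichment were largely at other genes. In the stimulated list they were at Atp6ap2 (24.9, chromosome X, 12615656 to 12616725), Id4 (21), Gm8882 (20.03, 99.7 kb away), Tut7 (19.7) and the histone demethylase gene Kdm1a (19.3). Then came peaks nearest to Bcl11a (17.8, 927 kb away), Slc22a5 (16.3), Fn1 (16.2, 177 kb away), Klhl6 (16.0), Gtf2ird1 (15.9), Ano2 (15.8), Trak1 (15.6), Marchf1 (15.3), Marcks (15, 125 kb away) and the ERK phosphatase gene Dusp6 (15). Of these 15, the Marchf1 peak did not overlap an unstimulated peak. The peaks nearest to Gm8882, Bcl11a, Marchf1 and Marcks were narrow, between 155 and 171 bp. The 8 unstimulated peaks of highest fold enrichment were nearest to Arid1b (16.8, 368 kb away), Kdm1a (16.7), Id4 (12.5), Atp6ap2 (12 and 11), Phactr1 (11, 115 kb away), Fn1 (10.8) and Tut7 (10.7), and all 8 overlapped a stimulated peak. Atp6ap2 held 6 stimulated peaks inside a gene body of 29.3 kb, 5 of them under 200 bp wide.

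Nearly all sites bound without added ligand were found again in the longer list after BMP9/10. Of the 1133 unstimulated peaks, 1087 overlapped a stimulated peak (95.9%, 95% interval 94.6 to 97.0), among them the peaks at Id1, Id2, Id3, Smad6, Smad7, Eng, Kdr and Klf2 named above. With the stimulated list shortened to the length of the unstimulated one, 735 did (64.9%). Random placements gave a mean of 0.911 and at most 5 overlaps with the full list (one-sided permutation p = 0.001, the smallest that 1000 placements can give). Such placements do not keep peaks in gene-rich or open regions, so they set a low bar. In the other direction, 1081 of the 4333 stimulated peaks (24.9%, 23.7 to 26.3) overlapped an unstimulated one. The 3252 stimulated peaks without an unstimulated counterpart had a median fold enrichment of 4.29 and a median width of 180 bp, and the 1081 with one had 5.80 and 320 bp.

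At the 1086 shared pairs outside mitochondrial DNA, the median IP pileup per 1000000 IP tags was 0.698 in the unstimulated and 1.05 in the stimulated list. The stimulated value was higher at 1068 pairs (98.3%), with a median ratio of 1.47 (interquartile range 1.29 to 1.68). The local background per 1000000 tags had a median ratio of 1.00 at the same pairs. The authors' fold enrichment at these pairs had medians of 4.0 (interquartile range 3.32 to 5.0) and 5.80 (4.50 to 7.26). Pairs had to be called in both lists to be counted here.

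Shared sites of the fixed lists' genes spread around this median. With each peak used once and the closest summits paired, the 77 such sites at 43 genes had ratios from 0.956, at Msx1, to 2.69, at Tgfbi (counting interval 1.61 to 4.64), and at 35 sites the counting interval lay above 1. Among BMP target genes 10 of 25 sites did so. The largest ratios there were 2.19 (1.46 to 3.33) beside Id1, 2.02 (1.32 to 3.14) at Atoh8 and 1.98 (1.24 to 3.19) near Id3. Smad7 had 1.72 (1.05 to 2.86) beside its gene end and 1.02 (0.482 to 2.12) inside the gene body. TGF-beta target genes had intervals above 1 at 13 of 19 sites, with 1.79 (1.16 to 2.77) inside Skil and 1.86 (1.26 to 2.79) near Snai1. The 2 housekeeping sites also had intervals above 1, with 1.90 (1.22 to 2.99) at Actb. Median ratios were 1.46 at BMP target, 1.61 at TGF-beta target and 1.74 at housekeeping sites, against 1.47 over all shared pairs. Intervals above 1 were not counted over all shared pairs. Such an interval therefore does not set a site apart from shared sites in general.

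**Figure D2:**
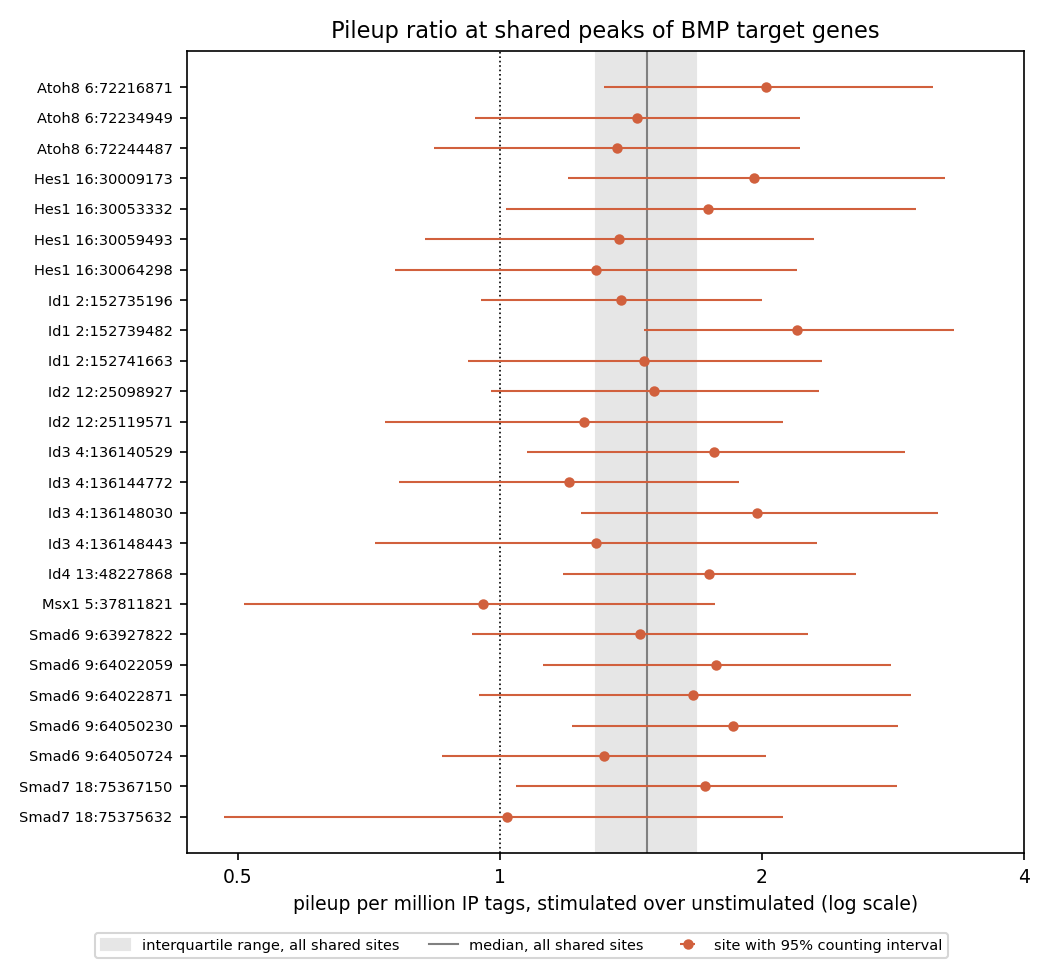
Ratio of IP pileup per 1000000 IP tags, stimulated over unstimulated, on a log x axis, for the 25 shared sites of 9 BMP target genes, labelled on the y axis by gene, chromosome and stimulated summit; bars are 95% counting intervals, the grey band and line give the interquartile range and median of all shared sites. Ratios run from 0.956 to 2.19 around the overall median of 1.47.

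The next comparison asked which gene groups had SMAD4 peaks nearby. Of 20 BMP target genes, 9 were nearest to an unstimulated peak, within 100 kb (1.13 in random lists, adjusted p = 0.000486, permutation test) and 12 to a stimulated one (3.54 in random lists, adjusted p = 0.00085, permutation test). Id1, Id2, Id3, Id4, Smad6, Smad7, Hes1, Atoh8 and Msx1 had peaks in both lists, and Bmper, Gata2 and Smurf1 were nearest to a stimulated and to no unstimulated peak within 100 kb. Of 19 TGF-beta target genes, 9 had an unstimulated peak (0.881 in random lists, adjusted p = 0.000486, permutation test) and 16 a stimulated one (2.85 in random lists, adjusted p = 0.000486, permutation test). The strongest stimulated peak of that group lay inside Skil (13.8), a nuclear repressor of SMAD signalling. The next were nearest to Pmepa1 (13.3, 59.4 kb away), Tgfbi (12.3, 8.76 kb away) and Snai1 (8.15, 32.2 kb away). Ccn1, Ccn2, Cdkn1a, Fn1, Ltbp2, Tgif1 and Thbs1 were nearest to a stimulated and to no unstimulated peak within 100 kb. With the stimulated list shortened to the length of the unstimulated one, 9 BMP target genes and 9 TGF-beta target genes had a stimulated peak.

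Endothelial identity and VEGF pathway genes also passed in both lists. Of 25 endothelial identity genes, 7 had an unstimulated peak (1.14 in random lists, adjusted p = 0.000486, permutation test) and 17 a stimulated one (3.55 in random lists, adjusted p = 0.000486, permutation test). Vwf (9.70), Egfl7 (8.88), Sox17 (7.78, 74.3 kb away) and Tal1 (7.20) had its highest stimulated fold enrichments. The Vwf peak was 129 bp wide and is among the tall narrow peaks whose origin is left open below. Without such peaks 16 genes had a stimulated peak. Cdh5, Cldn5, Egfl7, Emcn, Eng, Sox18 and Tal1 had peaks in both lists. The shortened stimulated list had 11. Of 17 VEGF pathway and tip cell genes, 5 had an unstimulated peak (adjusted p = 0.00816, permutation test) and 10 a stimulated one (adjusted p = 0.000486, permutation test). The strongest stimulated peaks were nearest to Apln (7.54, 18.7 kb away), Kdr (7.50, 10.0 kb away), Igfbp3 (6.67, 19.9 kb away) and Flt1 (6.57, 25.6 kb away). The shortened stimulated list had 4, fewer than the unstimulated list (adjusted p = 0.0408 over the 17 lists of that set alone, permutation test).

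The Notch pathway, flow response and PI3K, and arterial and venous identity passed in the stimulated list and not in the shorter unstimulated one. At equal list length 4, 4 and 1 of their genes had a peak in 1 list only, too few for a test of the difference. Notch pathway genes had 9 of 20 with a stimulated peak (2.66 in random lists, adjusted p = 0.00189, permutation test) and 3 with an unstimulated one (adjusted p = 0.102, permutation test). Hes1 (10.5, 56.2 kb away), Nrarp (6.74, 35.2 kb away), Lfng (5.80) and Jag1 (5.51) were its strongest stimulated members. The shortened stimulated list had 5 genes (adjusted p = 0.00892, permutation test). Flow response and PI3K genes had 11 of 20 (3.02 in random lists, adjusted p = 0.000486, permutation test) and 2 unstimulated (adjusted p = 0.407, permutation test). They were led by Edn1 (10.0, chromosome 13, 42301422 to 42301655), which encodes the vasoconstrictor endothelin-1, Klf2 (6.86), Klf4 (6.17) and Pecam1 (5.90). The shortened stimulated list had 4 (adjusted p = 0.0428, permutation test). That value is close to 0.05 and was adjusted over the 17 lists of that set alone. Arterial and venous identity genes had 6 of 16 (adjusted p = 0.0451, permutation test), among them Ephb4 (6.33), Jag1, Dll4 and Flt4 (4.44), but the shortened stimulated list had 2 (adjusted p = 0.287, permutation test).

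The remaining groups did not pass in either list. BMP and TGF-beta receptors, ligands and SMADs had 4 and 9 of 26 (adjusted p = 0.120 and 0.0615, permutation test), with stimulated peaks at Smad4 (9.08), Smad1 (6.58), Smad3 (6.33) and Bmp4 (6.29). Angiopoietin and TIE genes had 1 and 4 of 10 (adjusted p = 0.616 and 0.144, permutation test), the strongest being Ptprb (9.27) and Foxo1 (6.33, 41.4 kb away). Cell cycle genes had 3 and 5 of 20 (adjusted p = 0.0983 and 0.178, permutation test). These included Cdkn2b (6.84, 38.0 kb away), Myc (6.18), Ccnd1 (6.13, 85.0 kb away) and Mki67 (3.67). Markers of other cell types stayed near random lists. The stimulated list held 1 of 13 mural cell genes (Kcnj8), 2 of 12 fibroblast genes (Thy1, 97.8 kb away, and Pdgfra) and 2 of 14 leukocyte genes (Ptprc, 23.5 kb away, and Spi1). It also held 1 of 15 pancreatic islet and acinar genes (Ctrb1), 3 of 14 neuron genes (Snap25, Syn1 and, 33.0 kb away, Nefl) and 0 of 14 hepatocyte genes. Their adjusted p-values in that list were 0.616 or higher (permutation test). In the unstimulated list those groups had 1, 1, 1, 0, 0 and 0 genes. Housekeeping genes had 2 and 3 of 15 (0.309 and 1.07 in random lists, adjusted p = 0.0876 and 0.162, permutation test), more than random lists in both conditions. Random lists were not matched on expression or open chromatin, so a tendency of active genes in general to collect peaks was not tested.

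**Figure D3:**
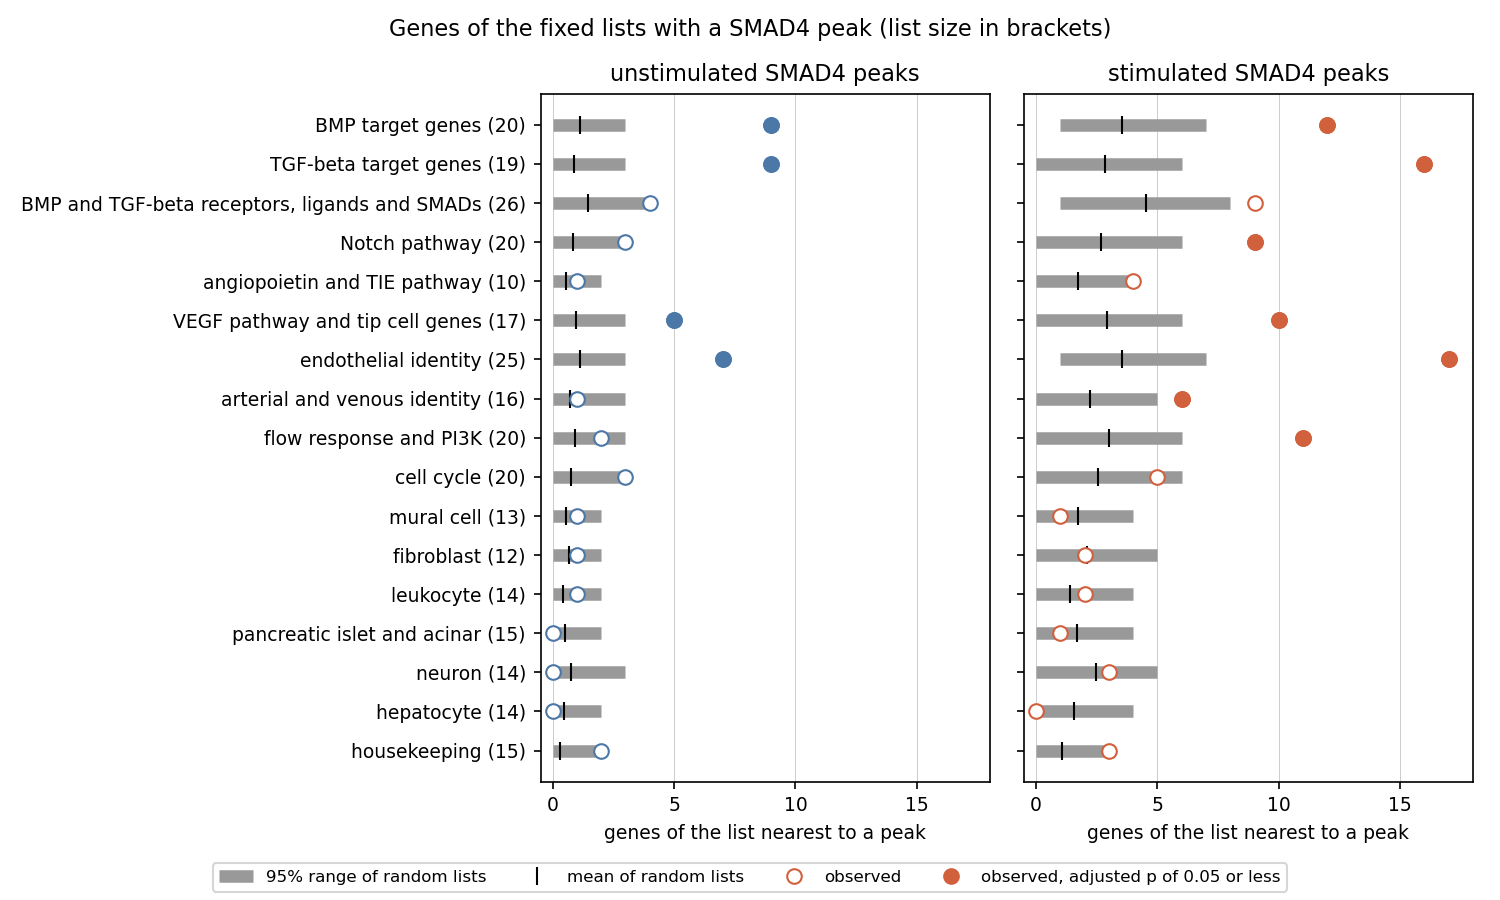
Number of genes of each fixed list (y axis, list size in brackets) that were nearest to a SMAD4 peak (x axis), in the unstimulated and stimulated lists; grey bars and black ticks give the 95% range and mean of 10000 random lists, and filled points have an adjusted p of 0.05 or less. TGF-beta target genes reach 16 of 19 and endothelial identity genes 17 of 25 in the stimulated list, while hepatocyte genes stay at 0.

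SMAD4 peaks lay near gene ends, as at Smad6, Smad7 and Edn1, more often than random positions. In the unstimulated list 165 of 1130 peaks (14.6%, 95% interval 12.6 to 16.8) lay within 1 kb of either end of a protein-coding gene, against 3.14% of random placements (permutation p = 0.001, the smallest possible). In the stimulated list 815 of 4324 did (18.8%, 17.7 to 20.05), against 3.14% of random placements (permutation p = 0.001, the smallest possible). Between the peaks of the lists Fisher's exact test, two-sided, gave p = 0.000803, but shared sites stand in both lists, so the groups were not independent. Stimulated peaks without an unstimulated counterpart had 20.3% (18.9 to 21.7). For these against the unstimulated peaks, Fisher's exact test, two-sided, gave p = 1.79e-05. The stimulated list shortened to the length of the unstimulated one had 16.1%, inside the unstimulated interval. Inside gene bodies lay 43.2% of unstimulated and 46.8% of stimulated peaks, against 41.0% and 40.9% of random placements (permutation p = 0.0679 and 0.001). In all, 830 protein-coding genes were nearest to an unstimulated peak, 2679 to a stimulated one and 811 to both.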

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

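No test was run or chosen after the result was seen in this part. Mitochondrial DNA, which the comparisons above leave out, carried 3 peaks in the unstimulated list and 9 in the stimulated list. Their fold enrichments were among the lowest of each list, from 1.67 to 1.83 and from 1.55 to 2.67. The local background there was 22.2 to 27.5 times the genome-wide background in the unstimulated list and 19.1 to 36.4 times in the stimulated list, and no explanation was tested.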

How the results depend on the processing

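Tests with curated genes, shifted peaks, without tall narrow peaks or with stimulated peaks that overlap no unstimulated peak were chosen after the results were seen. A −log10 q minimum of 10 left 371 unstimulated and 1551 stimulated peaks, since it removes peaks by construction. Arterial and venous identity genes no longer passed in the stimulated list at a −log10 q minimum of 5 (5 genes, adjusted p = 0.0581, permutation test), with the stimulated list at the length of the unstimulated one (2 genes, adjusted p = 0.287) or with stimulated peaks that overlap no unstimulated peak (5 genes, adjusted p = 0.0580), which all use fewer peaks. Housekeeping genes passed in the unstimulated list when any peak within 10 kb of a gene counted (3 genes, adjusted p = 0.0252, permutation test; the cause was not tested). The other 220 recomputed values kept their direction and their side of the threshold. For the shortened list and for stimulated peaks without an unstimulated counterpart, this holds with the adjustment over 17 lists alone. The share of unstimulated peaks with a stimulated counterpart ranged from 64.9%, with the stimulated list shortened, to 95.9%. No paired analysis was possible because the peaks were called on merged libraries and the replicate letters differ between the conditions. Leaving out a replicate was not possible for the same reason, and the motif alternatives were not run without a genome sequence.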

Other observations

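The tests of sequencing depth, of input background, of the number of peaks under a uniform gain, of the tallest peaks against simulated ones, of the peaks left after removing those in Atp6ap2 and of wide peaks matched on pileup were chosen after the result was seen. The unstimulated cutoff was also changed then, from the lowest called −log10 p to the median of the narrowest peaks, and the verdicts on the tallest peaks under a uniform gain and on both explanations of the tall narrow peaks moved from not fitting to open. The verdicts on input background, on a uniform gain at every site and for the number of peaks, and on open regions around shared peaks later became open too. Several genes, within the fixed lists and beyond them, collected many peaks, and they are named after their values were seen. Hes1 had the most, with 10 stimulated and 5 unstimulated peaks. Hs1bp3 (8 stimulated, 3 unstimulated), Ergic1 (8 and 3), Gse1 (8 and 2) and Frmd4a (8 and 2) followed. Dusp6, with a gene body of 4.26 kb, had 6 and 2. Myct1, an endothelial gene of 13.1 kb, had 4 peaks in each list, and Atoh8, a BMP target, had 5 and 3. Chromosome 12 had the most stimulated peaks per 100 protein-coding genes among autosomes (35.9), and chromosome X had 6.31.

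Atp6ap2 stood apart in how densely its peaks lay. This gene, an accessory subunit gene of the proton pump on chromosome X, held 20.5 stimulated peaks per 100 kb inside its gene body, the highest of the 18 genes with at least 5 peaks inside, ahead of Itgb3 with 9.60. Its 6 stimulated peaks ran from 102 bp to 1070 bp in width and 5 were under 200 bp. The widest (12615656 to 12616725) lay at the end of the gene body. In the unstimulated list it held 5 peaks with fold enrichments of 5.43 to 12. Smad4, with 7.25 per 100 kb, held 5 stimulated peaks (118 to 307 bp wide, fold enrichments 5.20 to 9.08) and 2 unstimulated ones, all inside its gene body on chromosome 18. Exon positions were not used here, so whether these narrow peaks coincide with exons was not tested.

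The stimulated list was 3.82 times longer than the unstimulated one, with 0.775 times the IP tags. Sequencing depth alone would have made the list with fewer tags the shorter one. As a stand-in for the unstimulated cutoff, the median −log10 p of 10.7 among the 99 narrowest peaks was used. Unstimulated peaks were called down to a −log10 p of 6.03, so 10.7 is not the limit of the caller. At equal pileup per tag 3248 of 4324 stimulated peaks would have passed 10.7, against the 1079 found. Lower input background stays open, because the median log2 background ratio of 0 at shared sites covers ratios that go both ways (SD 0.503), and the unstimulated background at peaks called after stimulation only was not measured. A uniform gain may account for the length of the list but was not shown to. Dividing every stimulated pileup by the median ratio of 1.47 predicts 1063 peaks past the stand-in cutoff of 10.7. This total is near 1079 only because of the cutoff chosen and because errors cancel. Of the 1079, 691 were called where predicted. At a −log10 q of 2 to 5 and 5 to 10 the prediction was 0, and 66 and 166 were called, while at 10 to 20 it was 634, and 467 were called. The median gain of 1.63 among peaks with a −log10 q of 20 or more, with uncalled ones ranked highest, would instead predict 325 in that last range and 753 in all. The lowest called −log10 p of 6.03 as the cutoff would give 2702, well above the 1079 found, so the predicted number depends on the cutoff. Under the worst-case background, a lenient bound, 0 peaks needed a gain above the highest at a shared peak (2.86). At equal background 2 did, nearest to Marchf1 (3.26) and Pou4f1 (2.92), and 419 needed more than the median gain. Both of these 2 peaks were narrow (157 and 146 bp) and are among the tall narrow peaks whose origin is left open below. Among peaks with a −log10 q of 20 or more, 88.6% of 429 were called in the unstimulated list, below the 100% from dividing by the median. In 1000 draws with the spread of ratios and backgrounds at shared sites, the share ran from a minimum of 87.4% to a maximum of 95.3% (mean 91.5%). The observed share lay near the minimum. That spread may itself hold site-specific gains, so the draws cannot exclude them. A site-specific gain was thus neither shown nor excluded for the 49 left uncalled, which include peaks at Edn1 and Ptprb. Of the 49, 10 were under 200 bp wide, against 20 among all 429, so narrow peaks were over-represented among the uncalled ones. Response to the ligand and a difference in yield between the pooled IPs cannot be told apart, since each condition is 1 pooled IP. The variance of the ratios over that of counting noise (0.651) decides nothing, because a response can be uniform and pairs had to be called in both lists.

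Some tall stimulated peaks were narrow: 34 had a fold enrichment of 8 or more and a width under 200 bp, among them those nearest to Gm8882, Bcl11a, Marchf1 and Vwf. Misplaced reads could produce such peaks away from other binding. Amplified copies at the same position could not, because at most 1 tag per position was kept. Another stimulated peak lay within 20 kb of 20.6% of the narrow peaks, against 35.3% of 224 tall wide peaks and 4.92% of random placements (permutation p = 0.002). Without the 3 peaks in Atp6ap2 the share was 12.9% (permutation p = 0.0809), so misplaced reads stay open as an explanation. An unstimulated peak overlapped 35.3% of the narrow and 79.9% of the wide ones, but 51.5% of 68 wide peaks matched on pileup (Fisher's exact test, two-sided, p = 0.144). Ligand-dependent sites of the same kind as the wide peaks therefore also stay open.

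Stimulated peaks without an unstimulated counterpart lay near sites bound in both lists more often than shifted or random positions did, as around Smad7 and Id3, although most lay elsewhere. Of 3245 such peaks, 13.0% lay within 20 kb of a shared peak, against at most 4.78% when the peaks were shifted by 50 to 250 kb and a mean of 1.60% at random positions. A gene-rich or open region narrower than 50 kb would be left behind by every shift, so the shifts cannot exclude such regions, and this explanation stays open. Some of these peaks lay directly beside a shared one, as at Smad7 (75367379 to 75367606, beside 75366438 to 75367227). Whether such neighbours are separate sites or parts of 1 enriched region was not tested, and every shift separates them. Peaks called after stimulation only may also be weaker existing sites below the unstimulated cutoff. Coverage of the unstimulated IP at these positions would tell new sites from weaker ones and was not analysed here, and no biological explanation was tested.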
